A study of Homo sapiens with 12 samples.

How the data were processed

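Poly(A) RNA of MCF-7 cells was sequenced in 12 libraries, 3 biological replicates in each of 4 groups (vehicle, estradiol, fulvestrant, and fulvestrant with estradiol), from 1 µg of total RNA per library with a directional kit. Per the labels, the authors aligned the reads to hg38 with HISAT2 2.2.1 and counted them per gene with featureCounts of Subread 2.0.1. The deposited values are raw counts per gene, with 1 column per library, and the deposited table also gives a length in bases for each gene, which was not used. The strand setting, the gene models and any filter on reads were not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain. How reads that match several genes were handled is likewise unknown, which matters for members of gene families such as PDZK1, the keratins and UGT1A6, which shares exons with other UGT1A genes, and for mitochondrially encoded transcripts, which have nuclear copies.

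The table had 27590 lines for 24433 Entrez gene identifiers. An identifier with several Ensembl names was repeated (1492 identifiers), always with the same counts, so 3157 extra lines were dropped. Symbols came from the table for 23753 identifiers and from RefSeq for 668, and 12 had none. Coordinates were those of RefSeq on GRCh38.p14, which held 24420 of the identifiers. After this the totals per library ranged from 28046331 to 34465313 counts. A count of 0 would allow up to 3 counts of the total, and since the reads carry no molecular identifiers this limit covers counting error only. The SD values describe the spread between the 3 replicates.

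Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 14409, and libraries were scaled with TMM factors. A quasi-likelihood negative binomial model with robust dispersion was fitted to all 12 libraries at once, with 1 mean per group, so that the 4 groups share 1 estimate of the spread. F tests were made for estradiol against vehicle, fulvestrant against vehicle, both compounds against estradiol, both against fulvestrant, both against vehicle, and the interaction (the effect of estradiol with fulvestrant minus its effect without). All tests were two-sided. A comparison of fulvestrant with estradiol was added after the data were seen. Adjusted p-values are from edgeR with the Benjamini-Hochberg method over the 14409 genes, and a gene is called changed at an adjusted p under 0.05. Log2 fold changes are given with their SE, and levels as TMM-scaled CPM. The fold change tests used counts alone, and CPM with a prior count of 2 on the log2 scale served the gene list tests and the principal components.

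These comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. For each comparison of 2 groups the rule takes, among genes past the threshold with a gene symbol, a mean of at least 2 CPM over the 12 libraries and no overlap between the 3 values of each group, the 8 with the largest rise and the 8 with the largest fall. For the interaction it takes 6 in each direction without the condition on overlap. ESR1, PGR, GREB1 and TFF1 are given in every comparison, and from each list up to 4 passing members with the smallest p, or the 2 most abundant where none passes. From these the text names the members that matter most. SPRY3, which the rule takes among the rises of both compounds against vehicle, is left out because it lies in a region shared by the X and Y chromosomes. TNFAIP2 is named outside the rule. The 22 lists, drawn from general knowledge and not from these samples, covered estrogen-induced and estrogen-repressed genes, DNA replication, mitosis, homologous recombination and repair, growth arrest, ribosome biogenesis, cholesterol synthesis, the unfolded protein and integrated stress response, interferon-stimulated genes, p53 targets, the BCL2 family, immediate early genes, aryl hydrocarbon receptor and glucocorticoid receptor targets, nuclear receptors and coregulators, luminal, basal, mesenchymal and immune or endothelial markers, mitochondrially encoded transcripts, and hypoxia and glycolysis. Some genes belong to more than 1 list, such as TP53INP1.

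Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation. The estimate came from the fit with no replicate term, so it also holds differences between replicate numbers. Adjustment was over the 21 lists with at least 5 tested members in each comparison. Counts of members that passed are given over all genes and adjusted over the list alone. The response to estradiol left under fulvestrant was measured as a slope through the origin across the genes estradiol changed, with a jackknife SE over the 12 libraries. Correlations of fold changes between comparisons that share libraries were set against 20 simulated sets without any change. A replicate number was taken to pair libraries of 2 groups where libraries of the same number resembled each other beyond their groups, with a correlation above 0.1 for every number. This held for both compounds with estradiol, both with fulvestrant, and fulvestrant with estradiol, and not for the comparisons with vehicle. The main fits did not model this pairing, so their SE, p-values and counts take differences between replicate numbers as spread. The replicate number as a block was run as an alternative.

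The test was checked on simulated data for both compounds against fulvestrant, with 50 of the 14409 genes changed at each of 4 sizes, 200 in all. At a true change of 1.25-fold 9 of 50 (18%) were recovered, at 1.5-fold 34 (68%), at 2-fold 33 (66%) and at 4-fold 48 (96%), with 10 false calls. The simulated libraries were drawn independently, with no effect of replicate number and no library set apart. The real libraries had both, so these shares may not hold for the real comparison.

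The alternatives tried were RLE size factors, library totals only, no count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of only the groups compared, an estimated correlation for the lists, and each library left out in turn. Leaving out the 4 libraries numbered 3 together, which had the highest mitochondrial shares, was added after the data were seen.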

Results

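Messenger RNA was measured by poly(A)-selected, directional sequencing in MCF-7, an established luminal breast cancer cell line that expresses the estrogen receptor. The cells were kept for 3 days in medium without phenol red and with 10% charcoal-stripped serum, which removes most steroid hormones, and were then treated for 24 hours. Libraries fell into 4 groups of 3 biological replicates, 12 in all: vehicle (DMSO), 1 nM estradiol (the main natural estrogen), 100 nM fulvestrant (an antagonist that binds the estrogen receptor and promotes its degradation), and 100 nM fulvestrant together with 1 nM estradiol. Total counts per library ranged from 28046331 to 34465313, so that 1 CPM (a count scaled to the library total) stood for 28 reads in the shallowest library. After a filter on low counts 14409 genes were tested.

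The first principal component held 50% of the variance of the 12 libraries. The estradiol libraries lay between 0.39 and 0.54 on it and the fulvestrant-containing libraries between -0.31 and -0.13, with the vehicle libraries in between. Of 12 immune and endothelial markers only 3 had enough reads to be tested, and none of these 3 changed in any comparison. Mitochondrially encoded transcripts, read here as a sign of RNA quality, took 3.7 ± 0.565% of counts with vehicle, 4.02 ± 0.955% with estradiol, 3.69 ± 0.582% with fulvestrant and 4.07 ± 0.861% with both compounds (mean ± SD, n = 3). In each group the library of replicate 3 had the highest share, at 4.32, 5.12, 4.33 and 5.07%. With estradiol, fulvestrant and both compounds this library also lay farther from the other replicates: chi-square per gene with it was 37.1 and 39.6, 13.4 and 16.1, and 30.6 and 30.7, against 8.84, 8.74 and 7.78 between replicates 1 and 2.

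The first comparison, estradiol against vehicle, asked which genes the hormone changes in steroid-deprived cells. Estradiol raised the classical targets of the estrogen receptor. GREB1, an estrogen-regulated cofactor of the receptor (Entrez 9687, GRCh38 chromosome 2, 11482888 to 11642788), went from 40.2 ± 2.44 to 260 ± 36.1 CPM (mean ± SD, n = 3), a 6.47-fold rise (log2 fold change 2.69 ± 0.09 SE, adjusted p = 1.5e-10). PGR, which encodes the progesterone receptor (Entrez 5241, chromosome 11, 101029624 to 101129813), rose 7.06-fold, from 0.759 ± 0.237 to 5.42 ± 0.783 CPM (adjusted p = 0.00012). TFF1, a secreted trefoil factor (Entrez 7031, chromosome 21, 42362282 to 42366535), rose 2.85-fold, from 956 ± 249 to 2730 ± 562 CPM (adjusted p = 0.0017). ESR1, the gene of the estrogen receptor alpha (Entrez 2099, chromosome 6, 151656672 to 152129619), stood at 279 ± 11.7 CPM with vehicle and 273 ± 12.4 CPM with estradiol (adjusted p = 0.81).

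In all, 2945 of the 14409 genes changed with estradiol, 1825 higher and 1120 lower, 258 of them at least 2-fold. The largest rises after GREB1 among genes averaging at least 2 CPM whose values did not overlap between the 2 groups were those of H19, an imprinted noncoding RNA (log2 fold change 2.46 ± 0.2 SE), the keratin KRT13 (2.45 ± 0.29), the scaffold protein gene PDZK1 (2.45 ± 0.21) and MSMB, which encodes a secreted microseminoprotein (2.34 ± 0.29). They were followed by the adenosine receptor ADORA1 (1.88 ± 0.22), GFRA1, a co-receptor for glial cell-derived neurotrophic factor (1.71 ± 0.19), and DHRS2 (1.64 ± 0.28). Their adjusted p-values ran from 9.2e-06 to 0.0018. The largest falls among such genes were those of SEMA5B (-1.85 ± 0.34), ADAMTS18 (-1.77 ± 0.41), MME, which encodes the peptidase neprilysin (-1.77 ± 0.36), and the acetylcholinesterase gene ACHE (-1.47 ± 0.18). Next came the potassium channel KCNJ13 (-1.43 ± 0.16), TP53INP2 (-1.28 ± 0.11), the connective tissue growth factor CCN2 (-1.27 ± 0.17) and the GABA-B receptor subunit GABBR2 (-1.22 ± 0.16), with adjusted p between 1e-05 and 0.0079. Without estradiol replicate 3 the fall of MME no longer passed (adjusted p = 0.052), and without vehicle replicate 2 the number of changed genes was 1772.

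**Figure D1:**
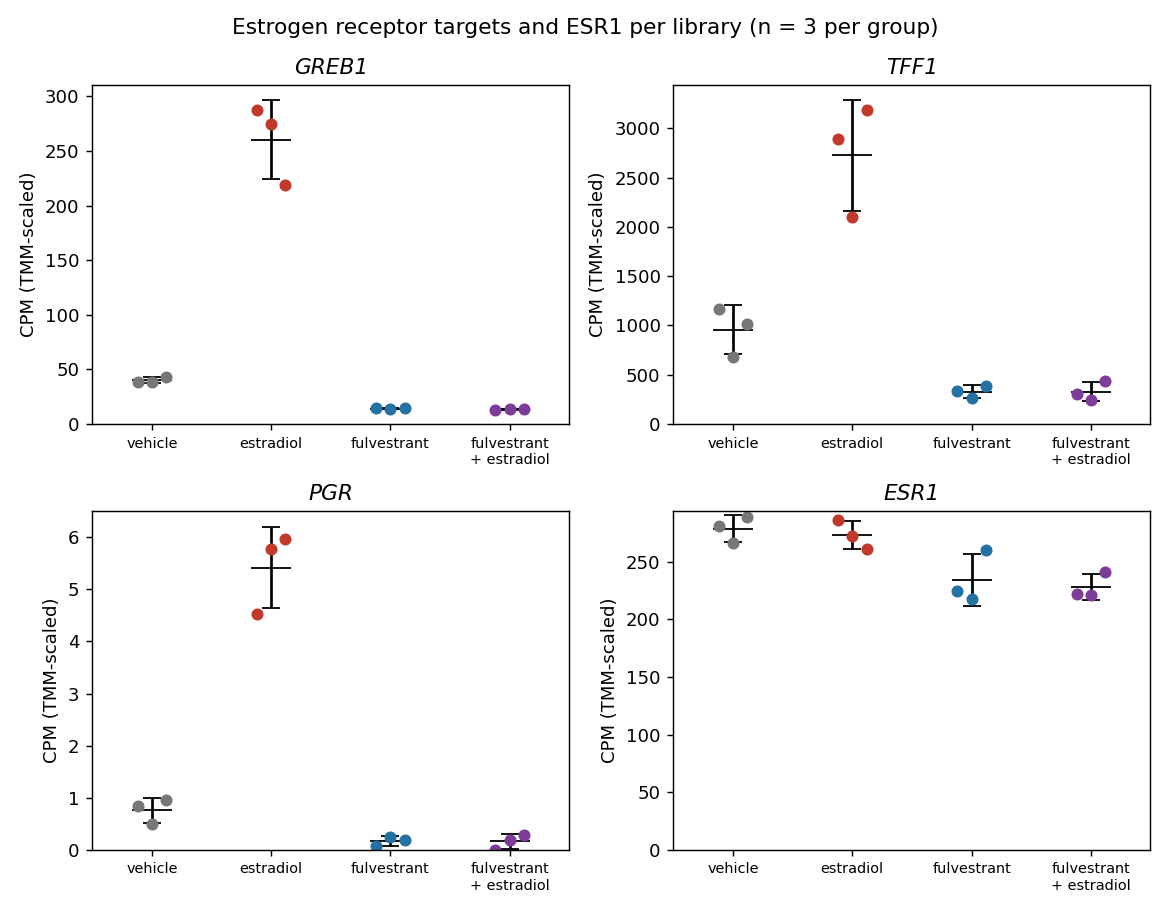
Level of GREB1, TFF1, PGR and ESR1 in each library (points, TMM-scaled CPM on linear axes that start at 0), with the mean (horizontal line) and SD (bars) of the 3 replicates of each group. GREB1 averaged 260 CPM with estradiol, 40.2 with vehicle, 14.1 with fulvestrant and 13.5 with both compounds, while ESR1 averaged between 228 and 279 CPM in the 4 groups.

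Genes of cell growth rose with the receptor targets. Of 29 tested estrogen-induced genes 25 rose with estradiol (26 adjusted over the list alone) and none fell, among them IGFBP4 (2.74-fold) and the transcription factor MYB (3.05-fold). Of 14 estrogen-repressed genes 11 fell (12 adjusted over the list alone), among them TP53INP1 (log2 fold change -0.99 ± 0.07), BLNK (-0.76 ± 0.08) and the interleukin receptor IL1R1 (-0.82 ± 0.1). All 28 genes of DNA replication and G1/S rose (28 adjusted over the list alone), including the helicase subunits MCM7 (0.8 ± 0.07) and MCM2 (0.86 ± 0.09) and their partner CDC45 (1.27 ± 0.13). All 26 mitosis genes rose (26 adjusted over the list alone), including ESPL1, which encodes separase (1.13 ± 0.12), and the spindle checkpoint protein BUB1B (1.1 ± 0.13). All 15 genes of homologous recombination and DNA repair rose (15 adjusted over the list alone), such as FANCD2 (0.89 ± 0.09) and XRCC2 (1.06 ± 0.12). Of 21 genes of ribosome biogenesis 16 rose (18 adjusted over the list alone), such as NOP56 (0.59 ± 0.06). In the set test (camera with a preset correlation) these 6 lists had adjusted p-values of 9e-18, 7.5e-10, 1.2e-20, 6e-17, 1.2e-12 and 1.1e-08, in the order given. With an estimated correlation the estrogen-induced and estrogen-repressed lists each kept an adjusted p of 0.02, while the adjusted p was 0.14 for replication, 0.18 for mitosis, 0.11 for repair and 0.059 for ribosome biogenesis.

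Other groups changed as well. Among 20 immediate early and growth factor response genes 9 fell with estradiol and none rose (9 adjusted over the list alone), including the transcription factors EGR1 (-0.99 ± 0.08) and JUNB (-0.54 ± 0.06). The list passed (adjusted p = 1e-04, and adjusted p = 0.18 with an estimated correlation), and 5 members fell without vehicle replicate 2 or vehicle replicate 3. Of 7 aryl hydrocarbon receptor targets 4 fell (4 adjusted over the list alone), ALDH1A3 by 0.9 ± 0.19 on the log2 scale and UGT1A6 among them (list adjusted p = 0.0074, and adjusted p = 0.18 with an estimated correlation). Of 19 genes of the unfolded protein and integrated stress response 9 rose (9 adjusted over the list alone), including ASNS, the asparagine synthetase (0.41 ± 0.08). That list passed at an adjusted p of 0.022, with an adjusted p of 0.63 under an estimated correlation, and lost its call without vehicle replicate 2 (adjusted p = 0.09), estradiol replicate 1 (adjusted p = 0.099) or the libraries of replicate 3 together (adjusted p = 0.053). In the BCL2 family 2 genes rose and 5 fell (2 and 6 adjusted over the list alone). The antiapoptotic BCL2 rose (1.14 ± 0.22), while the antiapoptotic BCL2L1 and the proapoptotic BBC3 and BMF fell (list adjusted p = 0.11, 0.034 without estradiol replicate 3, 0.025 without the 4 libraries of replicate 3, and 0.19 with all libraries and an estimated correlation).

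Among 13 growth arrest genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), including CDKN2B, a kinase inhibitor (-1.1 ± 0.16), and BTG1 (-0.43 ± 0.08). The median of that list was 0.02, its mean -0.14, and its set test pointed down (adjusted p = 0.17), and 3 members fell without any 1 of vehicle replicates 1, 2 and 3 or estradiol replicate 3. The glucose transporter SLC2A1 (0.71 ± 0.1) and LDHA, a lactate dehydrogenase subunit (0.64 ± 0.11), were 2 of the 4 hypoxia and glycolysis genes that rose among 16 (6 adjusted over the list alone, with 1 lower). Of 8 glucocorticoid receptor targets 3 rose, including FKBP5 (0.8 ± 0.11), and 3 fell (3 and 4 adjusted over the list alone), with a median of -0.26, a mean of 0.12 and a set test that pointed down (adjusted p = 0.58). Among p53 targets 3 rose and 4 fell (4 and 5 adjusted over the list alone). Of 22 cholesterol synthesis genes 4 rose with all libraries (5 adjusted over the list alone, with 1 lower), and 2, 1, 2 and 0 rose without vehicle replicates 1, 2 and 3 and estradiol replicate 3. Of 24 interferon-stimulated genes 1, IRF9, was lower (0 adjusted over the list alone, list adjusted p = 0.052), but 9 were lower without estradiol replicate 1 (list adjusted p = 9.1e-07). The list also passed without vehicle replicate 2 (adjusted p = 0.017), and with all libraries and an estimated correlation its adjusted p was 0.66. IRF9 itself lost its call without vehicle replicate 1, 2 or 3 (adjusted p = 0.095, 0.053 and 0.06) or estradiol replicate 2 or 3 (0.082 and 0.1). Nuclear receptors and coregulators had 3 higher and 1 lower (4 and 3 adjusted over the list alone; 3 lower without estradiol replicate 1 or 2). Luminal markers had 1 higher and 3 lower (1 and 3 adjusted over the list alone; 0 lower without vehicle replicate 2), and basal markers 2 higher and 1 lower (2 and 2 adjusted over the list alone). No gene passed among 9 mesenchymal and fibroblast markers or 13 mitochondrially encoded transcripts (0 adjusted over each list alone).

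Fulvestrant against vehicle asked what the antagonist does with no estradiol added. It lowered receptor targets below their level in steroid-deprived cells. GREB1 fell by 1.51 ± 0.09 on the log2 scale, to 14.1 ± 0.551 CPM (adjusted p = 1.1e-06), and TFF1 by 1.54 ± 0.25, to 329 ± 62.3 CPM (adjusted p = 0.0068). PGR went from 0.759 ± 0.237 to 0.169 ± 0.0974 CPM, a fall of few reads (2, 8 and 6 in the 3 fulvestrant libraries) that passed with all libraries (log2 fold change -2.15 ± 0.55, adjusted p = 0.044). It did not pass without vehicle replicate 1 (adjusted p = 0.14), vehicle replicate 3 (0.2), fulvestrant replicate 1 (0.19), fulvestrant replicate 2 (0.094) or fulvestrant replicate 3 (0.088). ESR1 stood at 234 ± 22.7 CPM (-0.25 ± 0.07, adjusted p = 0.076) and passed without fulvestrant replicate 3 (adjusted p = 0.016) and with DESeq2 (adjusted p = 0.044). It also passed with the replicate number as a block.

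With fulvestrant 487 genes changed, 71 higher and 416 lower, 63 of them at least 2-fold. The largest falls among genes averaging at least 2 CPM whose values did not overlap between the 2 groups were those of GFRA1 (log2 fold change -2.71 ± 0.23, adjusted p = 7.7e-05), the cytokine IL20 (-2.09 ± 0.2), the sulfatase SULF1 (-1.91 ± 0.31) and the Ras exchange factor RASGRP1 (-1.87 ± 0.15). They were followed by DTL, a substrate receptor of a ubiquitin ligase that acts in S phase (-1.8 ± 0.15, adjusted p = 1.3e-05), the protease TMPRSS3 (-1.77 ± 0.19), BCL2 (-1.7 ± 0.26) and KRT13 (-1.66 ± 0.34, adjusted p = 0.021). The largest rises among such genes were smaller. ACAA2, a mitochondrial thiolase, rose by 0.6 ± 0.07 (adjusted p = 0.00016), TP53INP2 by 0.73 ± 0.11 (adjusted p = 0.0012) and PSCA by 0.63 ± 0.1 (adjusted p = 0.0026), and these 3 passed without any 1 library. GFRA2 (1.06 ± 0.23), ACHE (0.91 ± 0.18), TSC22D3, the glucocorticoid-induced leucine zipper (0.75 ± 0.16), the protease PRSS22 (0.52 ± 0.1) and the calcium-binding S100P (0.49 ± 0.11) rose with all libraries, with adjusted p between 0.0084 and 0.022.

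Several of these calls were each lost in more than 1 of the fits with a library left out, which also leaves fewer libraries in that group. Without vehicle replicate 1 the adjusted p was 0.096 for GFRA2, 0.073 for TSC22D3, 0.096 for S100P and 0.062 for KRT13. Without vehicle replicate 2 it was 0.064 for S100P, and without vehicle replicate 3 it was 0.13 for GFRA2, 0.11 for TSC22D3, 0.063 for PRSS22, 0.096 for S100P and 0.089 for KRT13. Without fulvestrant replicate 1 it was 0.062 for ACHE, 0.083 for TSC22D3 and 0.06 for KRT13. Without fulvestrant replicate 2 it was 0.12 for GFRA2, 0.077 for ACHE, 0.067 for TSC22D3, 0.06 for PRSS22, 0.13 for S100P and 0.11 for KRT13, which also missed the threshold with limma-voom (0.064). The number of changed genes was 228 and 178 without vehicle replicates 1 and 3, 198 and 186 without fulvestrant replicates 1 and 2, 931 without the 4 libraries of replicate 3, 761 with DESeq2 and 838 in a fit of the 6 libraries compared. The genes that rose moved most: 14 rose and 164 fell without vehicle replicate 3, and 220 rose and 711 fell without the 4 libraries of replicate 3.

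Genes of DNA replication and repair fell with fulvestrant. Of 28 replication and G1/S genes 26 fell (28 adjusted over the list alone), including MCM2 (log2 fold change -0.93 ± 0.09) and CDC45 (-1.27 ± 0.14), with a list median of -0.82. Of 26 mitosis genes 7 fell (20 adjusted over the list alone), including ESPL1 (-0.94 ± 0.12), with a median of -0.56. Of 15 repair genes 14 fell (15 adjusted over the list alone), such as the helicase BLM (-0.97 ± 0.1) and BRCA1 (-0.78 ± 0.12). Of 21 ribosome biogenesis genes 9 fell (15 adjusted over the list alone), such as NOP56 (-0.45 ± 0.06). Of 29 estrogen-induced genes 18 fell (20 adjusted over the list alone), including MYC (-1.02 ± 0.09), MYB (-1.25 ± 0.16) and the potassium channel KCNK5 (-1.56 ± 0.17). Of 14 estrogen-repressed genes 4 rose (8 adjusted over the list alone, with 2 lower), TP53INP1 by 0.41 ± 0.06. The adjusted p-values of the set test were 1.9e-36 for replication, 4.5e-15 for mitosis, 5.1e-20 for repair, 3.7e-11 for ribosome biogenesis, 2.9e-20 for estrogen-induced and 1.2e-05 for estrogen-repressed genes. With an estimated correlation only mitosis among these 6 lost its call (adjusted p = 0.22).

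The smaller lists that passed were the BCL2 family (adjusted p = 0.0064, and adjusted p = 0.045 with an estimated correlation), in which BCL2 fell and BCL2L1 rose (0.25 ± 0.06; 2 rose and 1 fell adjusted over the list alone), the immediate early genes and the aryl hydrocarbon receptor targets. Of the immediate early genes (adjusted p = 0.0059, and adjusted p = 0.31 with an estimated correlation) EGR1 (0.42 ± 0.08) and JUNB (0.29 ± 0.06) rose (2 adjusted over the list alone). Of the aryl hydrocarbon receptor targets (adjusted p = 0.0046, and adjusted p = 0.17 with an estimated correlation) none passed singly (3 rose adjusted over the list alone). The glucose transporter SLC2A1 fell by 0.96 ± 0.1 and FKBP5 by 0.78 ± 0.11. The immediate early list lost its call without vehicle replicate 2 (adjusted p = 0.054) or fulvestrant replicate 1 (0.071), and the aryl hydrocarbon receptor list without fulvestrant replicate 1 (0.066). The cholesterol synthesis list (adjusted p = 0.3 with all libraries) passed camera without fulvestrant replicate 2 (0.016). EGR1 did not pass without vehicle replicate 1 (0.058) or fulvestrant replicate 2 (0.06). JUNB did not pass without vehicle replicate 2 or 3 or fulvestrant replicate 1 or 2 (0.063, 0.14, 0.1 and 0.12), nor BCL2L1 without any 1 of the 6 libraries compared (0.073 to 0.11).

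How many members of each list passed with fulvestrant moved when 1 library was left out. Mitosis genes that fell numbered 3, 4 and 1 without vehicle replicates 1, 2 and 3, 1, 1 and 16 without fulvestrant replicates 1, 2 and 3, and 26 without the 4 libraries of replicate 3. Estrogen-induced genes that fell numbered 10 without vehicle replicate 1 or 3 or fulvestrant replicate 2, and repair genes that fell numbered 8 without vehicle replicate 3 or fulvestrant replicate 2. Ribosome biogenesis genes that fell numbered 2 without vehicle replicate 1 or 3 or fulvestrant replicate 2, and 4 without fulvestrant replicate 1. Estrogen-repressed genes that rose numbered 1 without vehicle replicate 1 or fulvestrant replicate 1, and 2 without vehicle replicate 2 or 3 or fulvestrant replicate 2.

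**Figure D2:**
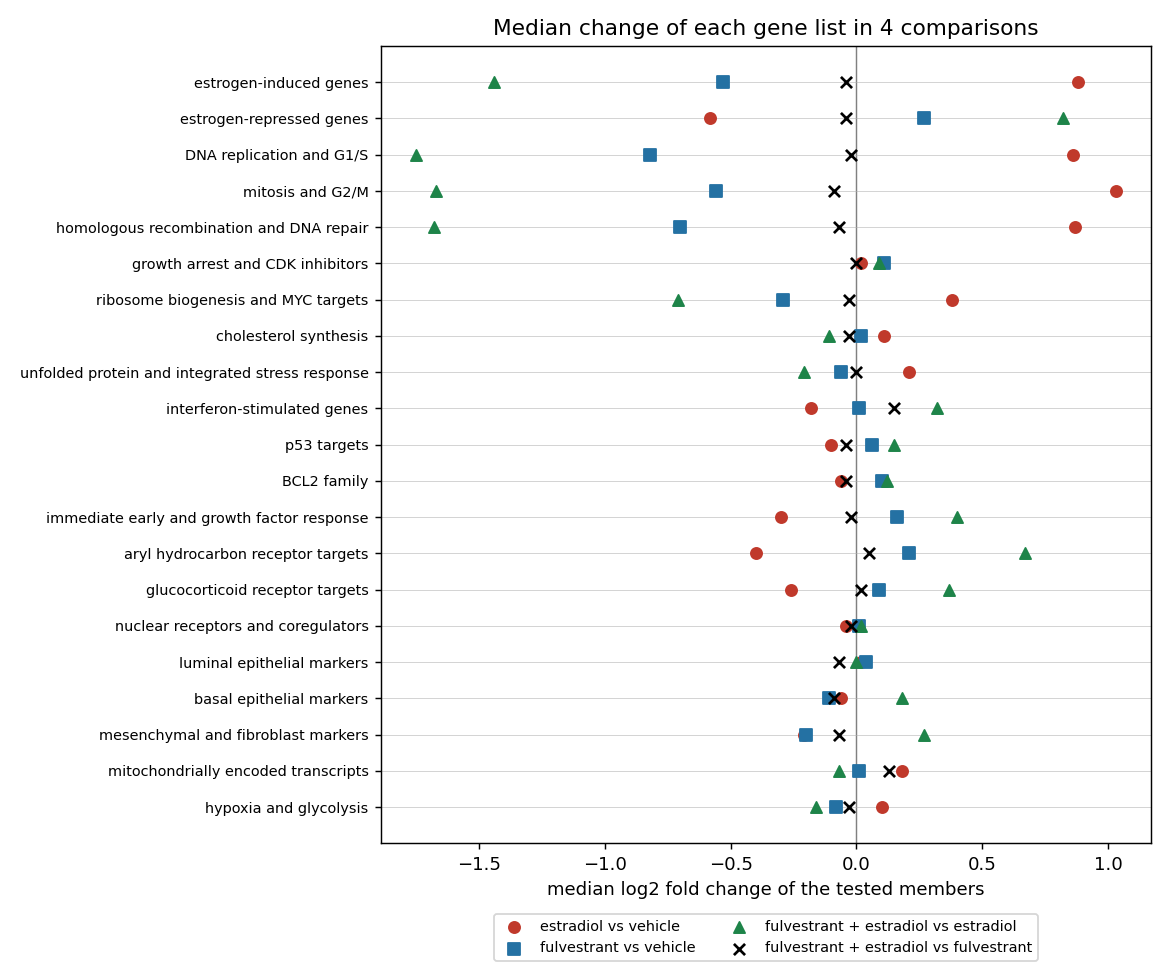
Median log2 fold change of the tested members of 21 gene lists (vertical axis) in 4 comparisons (symbols). Replication, mitosis, repair and estrogen-induced genes stand to the right of 0 with estradiol against vehicle (0.86, 1.03, 0.87 and 0.88) and to the left with fulvestrant against vehicle (-0.82, -0.56, -0.7 and -0.53), and lie within 0.09 of 0 between both compounds and fulvestrant alone.

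Adding fulvestrant to estradiol gave the widest change of the comparisons planned. GREB1 fell 19.3-fold, to 13.5 ± 0.368 CPM (log2 fold change -4.27 ± 0.1, adjusted p = 6.4e-13). PGR fell 33.8-fold, to 0.159 ± 0.147 CPM (0, 6 and 9 reads in the 3 libraries; adjusted p = 7.1e-07), and TFF1 8.32-fold, to 328 ± 97.6 CPM (adjusted p = 3.8e-06). ESR1 fell to 228 ± 11 CPM (-0.26 ± 0.07, adjusted p = 0.0094). The largest other falls among genes averaging at least 2 CPM whose values did not overlap between the 2 groups were those of KRT13 (29.2-fold, -4.87 ± 0.35), GFRA1 (-4.62 ± 0.23), PDZK1 (-4.04 ± 0.23), SULF1 (-3.82 ± 0.31), ADORA1 (-3.6 ± 0.25), MSMB (-3.59 ± 0.32) and KCNK5 (-3.4 ± 0.17), with adjusted p of 7.4e-07 or less. The largest rises among such genes were those of MME (2.8 ± 0.36), ADAMTS18 (2.67 ± 0.39), ACHE (2.2 ± 0.19), SEMA5B (2.2 ± 0.33), TP53INP2 (2.18 ± 0.11), TMEM151A (1.83 ± 0.25), AASS, an enzyme of lysine degradation (1.79 ± 0.3), and KCNJ13 (1.78 ± 0.16), with adjusted p between 5.3e-09 and 0.00058. Altogether 5915 genes differed between both compounds and estradiol alone, 2702 higher and 3213 lower, 857 of them at least 2-fold.

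Most of the gene groups that estradiol had raised fell when fulvestrant was added. All 28 replication genes (28 adjusted over the list alone; CDC45 -2.58 ± 0.14, MCM7 -1.56 ± 0.07), all 26 mitosis genes (26 adjusted over the list alone; ESPL1 -2.19 ± 0.12) and all 15 repair genes (15 adjusted over the list alone; FANCD2 -1.54 ± 0.09) fell. The same held for 26 of 29 estrogen-induced genes (28 adjusted over the list alone; MYC -1.88 ± 0.09) and 18 of 21 ribosome biogenesis genes (19 adjusted over the list alone; NOP56 -1.05 ± 0.06). In the stress response list, which estradiol had also raised, 11 of 19 fell and 3 rose (11 and 3 adjusted over the list alone; 1 rose without estradiol replicate 3). That list did not pass (adjusted p = 0.088, 0.73 with an estimated correlation, and 0.033 without estradiol replicate 2). Of 14 estrogen-repressed genes 12 rose and 1 fell (12 and 2 adjusted over the list alone), with TP53INP1 at 1.49 ± 0.07. Immediate early genes rose in 11 of 20 cases and fell in 1 (11 and 1 adjusted over the list alone), EGR1 by 1.49 ± 0.08. Of aryl hydrocarbon receptor targets 6 of 7 rose (6 adjusted over the list alone), ALDH1A3 by 1.49 ± 0.18 and CYP1A1, a cytochrome of xenobiotic metabolism, by 1.09 ± 0.2. In the BCL2 family 6 of 14 rose and 2 fell (7 and 2 adjusted over the list alone): BCL2 fell (-2.83 ± 0.25) while BCL2L1 (0.62 ± 0.06) and MCL1, another antiapoptotic member, rose (0.39 ± 0.06). In hypoxia and glycolysis 7 of 16 fell and 1 rose (7 and 1 adjusted over the list alone), SLC2A1 by 1.74 ± 0.1 and LDHA by 1.03 ± 0.12 among the falls. Among luminal markers KRT19 fell (-0.71 ± 0.09) and ELF3 rose (0.69 ± 0.1), with 4 of 17 higher and 2 lower in all (3 and 1 adjusted over the list alone). Among 9 basal markers 2 fell, the keratins KRT15 (-1.03 ± 0.11) and KRT16 (-1.27 ± 0.18), and 2 rose (2 and 2 adjusted over the list alone), CDH3 (0.28 ± 0.06) and ITGB4 (0.34 ± 0.1). ITGB4 did not pass without estradiol replicate 3 (adjusted p = 0.063) or replicate 1 or 2 of both compounds (0.058 and 0.072). None of the BCL2, glycolysis, luminal and basal lists passed as a whole (adjusted p = 0.11, 0.11, 0.71 and 0.89).

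In the set test the adjusted p-values were 8.9e-22 for replication, 2.1e-16 for mitosis, 4.3e-13 for repair, 2e-17 for estrogen-induced, 9.9e-07 for estrogen-repressed, 5.6e-10 for ribosome biogenesis, 0.00044 for immediate early genes and 0.0039 for aryl hydrocarbon receptor targets. With an estimated correlation the estrogen-induced, estrogen-repressed and ribosome lists each kept an adjusted p of 0.039, against an adjusted p of 0.13 for replication, 0.19 for mitosis, 0.11 for repair, 0.19 for immediate early genes and 0.19 for aryl hydrocarbon receptor targets. Interferon-stimulated genes also passed (adjusted p = 0.038, and adjusted p = 0.73 with an estimated correlation): IRF9 rose by 0.58 ± 0.12, IRF7 by 0.56 ± 0.14 and STAT1 by 0.74 ± 0.22, 3 of 24 (3 adjusted over the list alone). That call was lost without estradiol replicate 2 (adjusted p = 0.21), estradiol replicate 3 (0.13), replicate 1 given both compounds (0.27) or the 4 libraries of replicate 3 (0.19), and with library totals only (0.053). STAT1 lost its own call without the first 3 of these libraries (0.068, 0.089 and 0.074), and 12 members rose without estradiol replicate 1.

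Both compounds against fulvestrant alone asked which response to estradiol is left while the receptor is blocked. No gene passed: of 14409 genes 0 changed in edgeR, where the smallest adjusted p was 0.739, 301 had an unadjusted p under 0.05 against 720.5 expected by chance, and limma-voom called 0 (312 unadjusted) and DESeq2 1 (276 unadjusted). The gene DESeq2 called, named here after its values were seen, was TNFAIP2 (log2 fold change -0.58, adjusted p = 0.0049, against 0.74 in edgeR). The estradiol targets differed little. GREB1 stood at 13.5 ± 0.368 CPM with both compounds and 14.1 ± 0.551 CPM with fulvestrant (-0.07 ± 0.1, 95% interval -0.26 to 0.12) and TFF1 at 328 ± 97.6 and 329 ± 62.3 CPM (95% interval of the log2 fold change -0.49 to 0.48). PGR stood at 0.159 ± 0.147 and 0.169 ± 0.0974 CPM (-1.53 to 1.31), and ESR1 at 228 ± 11 and 234 ± 22.7 CPM (-0.18 to 0.1).

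Across the 2945 genes that estradiol changed, the slope of their fold changes in this comparison on those of estradiol against vehicle was -0.024 (jackknife SE 0.14, 95% interval -0.29 to 0.24), where 1 would be a full response and 0 none. Leaving out 1 library at a time moved the slope between -0.118 (without replicate 3 of both compounds) and 0.06 (without fulvestrant replicate 3). The 2 fold changes share no library, and genes are not independent replicates. Of the 258 genes changed at least 2-fold by estradiol 188 (72.9%) stayed within 1.2-fold. Their median absolute log2 fold change, over all 258, was 0.13, against 1.17 with estradiol alone, although single genes differed by up to 2.66. For 247 the 95% interval excluded the size of the effect of estradiol alone, taken without its own error and used to select these genes. The interaction, which counts both errors, passed as negative for 771 (42.2%) of the 1825 genes raised by estradiol. It passed as positive for 315 (28.1%) of the 1120 lowered. The interaction holds the effect of estradiol alone with the opposite sign, and these genes were selected on that effect. Selection alone therefore favours these directions, and the shares are not independent support.

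**Figure D3:**
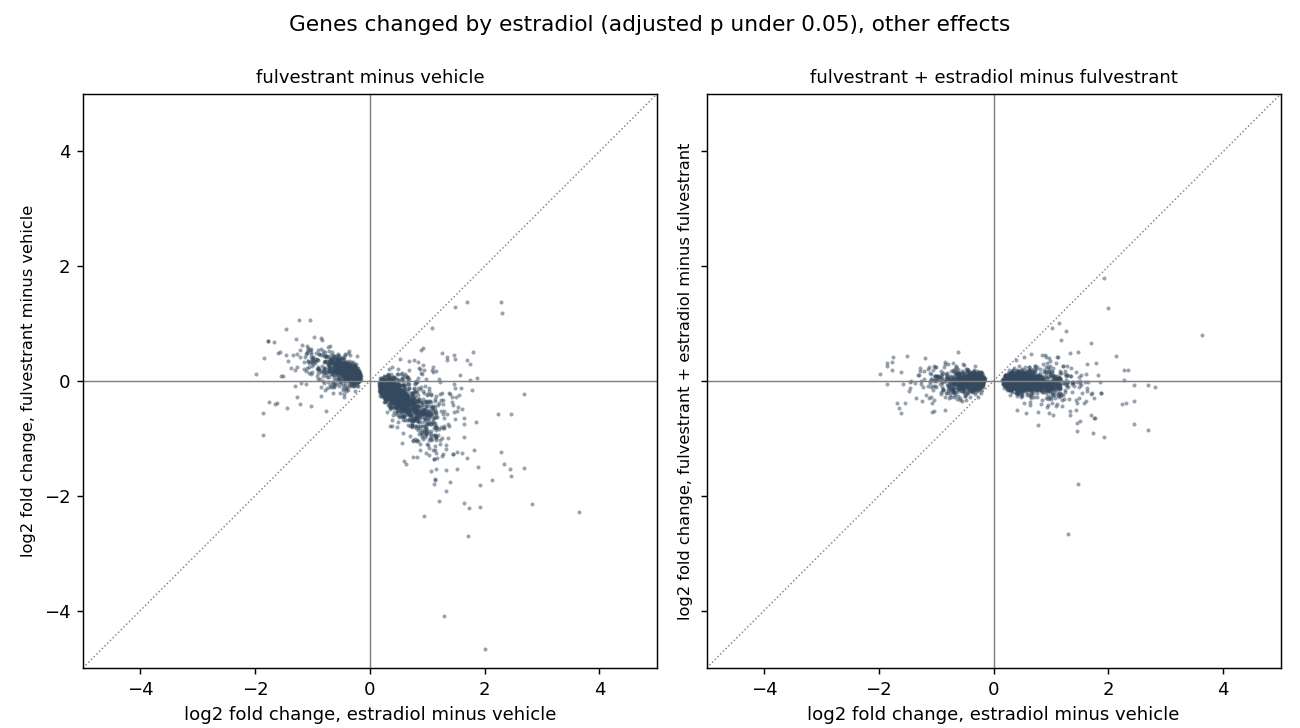
Genes changed by estradiol (points, adjusted p under 0.05), with the log2 fold change of estradiol minus vehicle on the horizontal axes and that of fulvestrant minus vehicle (left) or both compounds minus fulvestrant (right) on the vertical axes; the dotted line marks equal values. On the left the points run from upper left to lower right, with 390 genes both raised by estradiol and lowered by fulvestrant, and on the right they lie along 0, with a slope of -0.024.

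Of the gene groups 2 passed between both compounds and fulvestrant alone, both lower with estradiol added and neither with a member that passed over all genes. Luminal markers had a median of -0.07 (adjusted p = 0.03, and adjusted p = 0.82 with an estimated correlation; 0 of 17 adjusted over the list alone). Basal markers had a median of -0.09 (adjusted p = 0.025, and adjusted p = 0.82 with an estimated correlation; 2 of 9 lower adjusted over the list alone). The luminal call was lost without fulvestrant replicate 3 (adjusted p = 0.22) or replicate 1 or 2 of both compounds (0.3 and 0.15), and the basal call without fulvestrant replicate 1 (0.14) or replicate 3 of both compounds (0.077). With the replicate number as a block 4 lists passed, the additional 2 being mitochondrially encoded transcripts (adjusted p = 7.5e-05) and mitosis genes (adjusted p = 0.016), each with an adjusted p of 0.82 under an estimated correlation without the block. The number of lists was 1 without replicate 1 of both compounds, 6 without their replicate 3 and 7 without fulvestrant replicate 2. Mitosis genes, with a median of -0.09 and an adjusted p of 0.075 with all libraries (0.82 with an estimated correlation), passed as lower without fulvestrant replicate 1 (0.0022), fulvestrant replicate 2 (5.3e-05) or replicate 3 of both compounds (1.4e-10), without the 4 libraries of replicate 3 (8.3e-05), and with library totals only (0.042). Without fulvestrant replicate 2 and without replicate 3 of both compounds, replication (0.0059 and 1e-05), repair (0.036 and 0.0067), estrogen-induced (0.036 and 0.0067) and cholesterol synthesis genes (0.013 and 0.0067) passed as lower too. Mitochondrially encoded transcripts passed as higher without fulvestrant replicate 3 (0.0043) or replicate 2 of both compounds (0.012), and interferon-stimulated genes without the latter (0.0082). With all libraries and an estimated correlation each of these 6 lists had an adjusted p of 0.82. Replicate 3 had the highest mean of mitosis genes with fulvestrant (5.55 log2 CPM, against 5.1 and 5.04) and with both compounds (5.51, against 4.95 and 4.99). Leaving out 1 library of these pairs can therefore shift such lists without an effect of estradiol. The fit without the 4 libraries of replicate 3 is not open to this. It leaves 2 libraries per group, however, and its list test used the preset correlation only. In that fit 0 of 26 mitosis genes passed over all genes, so it does not decide whether estradiol lowered them.

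Cells given both compounds were also set against vehicle, to see whether they returned to the state of untreated cells. They did not: 599 genes differed, 74 higher and 525 lower, and the receptor targets lay below vehicle. GREB1 fell by 1.58 ± 0.09 on the log2 scale (adjusted p = 6.1e-07) and TFF1 by 1.55 ± 0.25 (adjusted p = 0.0052), near their values with fulvestrant alone. GFRA1 (-2.91 ± 0.23), SULF1 (-2.49 ± 0.33), KRT13 (-2.42 ± 0.37), KCNK5 (-2.07 ± 0.17), DTL (-2.05 ± 0.15), IL20 (-1.83 ± 0.2), TMPRSS3 (-1.8 ± 0.19) and FAM111B (-1.73 ± 0.21) had the largest falls among genes averaging at least 2 CPM whose values did not overlap between the 2 groups, with adjusted p between 5.5e-06 and 0.0034. TP53INP2 rose by 0.9 ± 0.11 (adjusted p = 0.00017), MIR22HG, the host transcript of a microRNA, by 0.62 ± 0.12 (adjusted p = 0.0055) and ACAA2 by 0.56 ± 0.07 (adjusted p = 2e-04). TMEM151A (0.85 ± 0.23), TSC22D3 (0.76 ± 0.16), ACHE (0.73 ± 0.18) and ZNF223 (0.6 ± 0.15) rose and PGR (-2.26 ± 0.55, adjusted p = 0.031) and ESR1 (-0.29 ± 0.07, adjusted p = 0.033) fell with all libraries.

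Each of those 6 calls was lost in more than 1 of the fits with a library left out, so none can be laid to a single library. Without vehicle replicate 1 the adjusted p was 0.14 for TMEM151A, 0.058 for TSC22D3, 0.075 for ACHE, 0.087 for ZNF223, 0.11 for PGR and 0.12 for ESR1. Without vehicle replicate 3 it was 0.24, 0.083, 0.095, 0.18, 0.15 and 0.16 in the same order. Without replicate 1 of both compounds it was 0.18 for TMEM151A, 0.1 for ACHE, 0.16 for ZNF223, 0.081 for PGR and 0.14 for ESR1. Without their replicate 2 it was 0.22 for TMEM151A, 0.064 for TSC22D3, 0.17 for ACHE, 0.095 for ZNF223, 0.095 for PGR and 0.15 for ESR1, and without vehicle replicate 2 it was 0.057 for TMEM151A and 0.063 for ZNF223. TMEM151A also missed the threshold with library totals only (0.057) and limma-voom (0.065), and PGR with limma-voom (0.053). The number of genes was 308 and 257 without vehicle replicates 1 and 3, 291 and 279 without replicates 1 and 2 of both compounds, 1481 without the 4 libraries of replicate 3, and 924 with DESeq2.

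By group, 27 of 28 replication genes lay below vehicle with both compounds (27 adjusted over the list alone; MCM2 -0.98 ± 0.09), as did 11 of 26 mitosis genes (23 adjusted over the list alone; ESPL1 -1.06 ± 0.12). So did 14 of 15 repair genes (14 adjusted over the list alone; BLM -1.05 ± 0.1) and 11 of 21 ribosome biogenesis genes (15 adjusted over the list alone; NOP56 -0.46 ± 0.06). Of estrogen-induced genes 18 of 29 were lower (22 adjusted over the list alone; MYC -1.1 ± 0.09). Estrogen-repressed genes passed as a list (adjusted p = 0.0032) with 2 members higher and 1 lower (7 and 2 adjusted over the list alone). The adjusted p-values of the set test were 9.9e-36, 1.7e-17, 1.6e-19, 2.6e-12 and 2.4e-21 for the first 5 groups. With an estimated correlation ribosome biogenesis (adjusted p = 0.031) and estrogen-induced genes (0.023) kept their calls, while the adjusted p was 0.051 for replication, 0.22 for mitosis, 0.05 for repair, just above the threshold before rounding, and 0.13 for estrogen-repressed genes. Mitosis genes that fell numbered 3 without vehicle replicate 3 or replicate 1 of both compounds, 2 without replicate 2 and 24 without replicate 3 of both compounds. Estrogen-induced genes that fell numbered 10 without vehicle replicate 1 or 3 and 11 without replicate 2 of both compounds, and ribosome genes that fell 5 without vehicle replicate 1 or 3 or replicate 1 or 2 of both compounds. Immediate early genes and aryl hydrocarbon receptor targets also passed (both adjusted p = 0.015, and adjusted p = 0.41 and 0.26 with an estimated correlation). EGR1 was the 1 immediate early gene that rose, by 0.5 ± 0.08 (2 rose and 1 fell adjusted over the list alone), and no aryl hydrocarbon receptor target passed singly (2 rose adjusted over the list alone). The immediate early call was lost without vehicle replicate 2 (0.087) or replicate 1 or 3 of both compounds (0.1 and 0.051), and the aryl hydrocarbon receptor call without replicate 1 of both compounds (0.1). Without the 4 libraries of replicate 3 both calls were lost (0.07 and 0.068). Other lists passed camera only without a library. Hypoxia and glycolysis did so without vehicle replicate 2 (0.039) or replicate 1 of both compounds (0.034). Mitochondrially encoded transcripts did so without vehicle replicate 3 (0.014) or replicate 2 of both compounds (0.03), and interferon-stimulated genes without the latter (0.0053). With all libraries their adjusted p was 0.12, 0.29 and 0.17.

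The interaction tested directly whether the effect of estradiol differed with and without fulvestrant. It did for 1105 genes, 323 with a more positive and 782 with a more negative effect of estradiol under fulvestrant. Among genes averaging at least 2 CPM, the largest negative values were those of KRT13 (-3.21 ± 0.5), H19 (-2.8 ± 0.29), GREB1 (-2.76 ± 0.13, adjusted p = 2.4e-08), PDZK1 (-2.51 ± 0.36), MSMB (-2.15 ± 0.52) and ADORA1 (-2.09 ± 0.36). The largest positive values among the same genes were those of MME (2.1 ± 0.48), ADAMTS18 (1.97 ± 0.52), SEMA5B (1.8 ± 0.44), SESN3, a sestrin (1.6 ± 0.26), TP53INP2 (1.45 ± 0.15) and KCNJ13 (1.44 ± 0.22). PGR (-2.93 ± 0.84, adjusted p = 0.047) and TFF1 (-1.52 ± 0.35, adjusted p = 0.024) passed, and ESR1 did not (-0.01 ± 0.1, adjusted p = 0.97). Of these genes KRT13, H19, GREB1, PDZK1, ADORA1, SESN3, TP53INP2 and KCNJ13 passed without any 1 library.

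The other named interaction calls were each lost in more than 1 of the fits with a library left out, and the count moved in these fits. MME did not pass without vehicle replicate 2 (adjusted p = 0.059), estradiol replicate 3 (0.098), fulvestrant replicate 3 (0.059) or replicate 2 of both compounds (0.071). SEMA5B did not pass without vehicle replicate 2 (0.066), fulvestrant replicate 3 (0.051) or replicate 1 or 2 of both compounds (0.06 each), nor MSMB without fulvestrant replicate 3 (0.11) or replicate 1 of both compounds (0.052). TFF1 did not pass without vehicle replicate 2 (0.052), estradiol replicate 3 (0.095), fulvestrant replicate 3 (0.065) or replicates 1 or 2 of both compounds (0.051 and 0.077). ADAMTS18 did not pass without vehicle replicate 1 or 2 (0.072 and 0.097), estradiol replicate 1 or 3 (0.06 and 0.074), fulvestrant replicate 2 or 3 (0.05 and 0.069) or replicate 1 or 2 of both compounds (0.088 and 0.085), or with limma-voom (0.063). PGR passed with all libraries and without fulvestrant replicate 1 or replicate 3 of both compounds, but its adjusted p lay between 0.053 and 0.18 without any 1 of the other 10 libraries and was 0.052 with library totals only. The number of genes was 700 and 557 without vehicle replicates 1 and 2, 640 without fulvestrant replicate 3, and 618, 595 and 1791 without replicates 1, 2 and 3 of both compounds. With the replicate number as a block it was 2729.

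Most of the groups that passed this test had also passed with estradiol alone. The effect of estradiol was more negative under fulvestrant for 22 of 29 estrogen-induced genes (25 adjusted over the list alone; IGFBP4 -1.47 ± 0.17) and 27 of 28 replication genes (28 adjusted over the list alone; MCM7 -0.9 ± 0.1). The same held for 23 of 26 mitosis genes (26 adjusted over the list alone; BUB1B -1.19 ± 0.19), 12 of 15 repair genes (15 adjusted over the list alone; FANCD2 -0.96 ± 0.13) and 12 of 21 ribosome genes (15 adjusted over the list alone; NOP56 -0.6 ± 0.09). The effect was more positive for 7 of 14 estrogen-repressed genes (10 adjusted over the list alone; TP53INP1 1.08 ± 0.09) and 4 of 20 immediate early genes (4 adjusted over the list alone; EGR1 1.08 ± 0.11). The adjusted p of the set test was 8.9e-20, 3.7e-22, 1.7e-18, 2.9e-13, 5.1e-09, 2e-08 and 0.00035 in that order. With an estimated correlation the estrogen-induced and estrogen-repressed lists each kept an adjusted p of 0.019, against an adjusted p of 0.12 for replication, 0.2 for mitosis, 0.1 for repair, 0.052 for ribosome biogenesis and 0.22 for immediate early genes. Mitosis genes numbered 14 without vehicle replicate 2 or replicate 2 of both compounds and 15 without estradiol replicate 3. Ribosome genes numbered 7 without vehicle replicate 1 or fulvestrant replicate 3 and 6 without vehicle replicate 2 or replicate 1 of both compounds, and immediate early genes numbered 2 without vehicle replicate 1 or 3, estradiol replicate 3 or replicate 1 of both compounds.

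The list of the stress response (adjusted p = 0.04; 2 members lower, and 6 lower with 1 higher adjusted over the list alone) passed the interaction as well. So did interferon-stimulated genes (adjusted p = 0.019; 0 members, 0 adjusted over the list alone) and aryl hydrocarbon receptor targets (adjusted p = 0.019; 1 higher, 3 adjusted over the list alone). None of these 3 passed with an estimated correlation (adjusted p = 0.71, 0.72 and 0.25). The stress response call was lost without vehicle replicate 2 (0.16), estradiol replicate 1 or 3 (0.14 and 0.074), fulvestrant replicate 1 (0.2) or replicate 2 of both compounds (0.13). In it 4 members were lower without estradiol replicate 2 and 7 without replicate 3 of both compounds. The interferon call was lost without vehicle replicate 1 (0.058), estradiol replicate 2 or 3 (0.17 and 0.12) or replicate 1 of both compounds (0.25), and 7 members were higher without estradiol replicate 1. Without the 4 libraries of replicate 3 the aryl hydrocarbon receptor (0.12) and interferon (0.24) calls were lost. Hypoxia and glycolysis (adjusted p = 0.086 with all libraries) passed camera in some fits, such as without vehicle replicate 1 (0.042) or estradiol replicate 2 (0.038).

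Estradiol and fulvestrant are related molecules: fulvestrant is a steroidal analogue of estradiol that carries a long alkylsulfinyl side chain. They were compared with each other after the data were seen, at doses that differ, 1 nM and 100 nM, so the values stand side by side. GREB1 averaged 260 ± 36.1 CPM with estradiol and 14.1 ± 0.551 CPM with fulvestrant (fulvestrant minus estradiol -4.2 ± 0.1, adjusted p = 7.7e-13). TFF1 averaged 2730 ± 562 and 329 ± 62.3 CPM (-3.05 ± 0.27, adjusted p = 4e-06) and PGR 5.42 ± 0.783 and 0.169 ± 0.0974 CPM (-4.97 ± 0.45, adjusted p = 9e-07). ESR1 averaged 273 ± 12.4 and 234 ± 22.7 CPM (-0.22 ± 0.07, adjusted p = 0.023), and did not pass without estradiol replicate 1 (0.083) or fulvestrant replicate 1 or 2 (0.092 and 0.11). Of 14409 genes 5797 differed, 2577 higher and 3220 lower with fulvestrant. All 28 replication, all 26 mitosis and all 15 repair genes were lower with fulvestrant (28, 26 and 15 adjusted over the list alone), as were 28 of 29 estrogen-induced genes (28 adjusted over the list alone). Of 14 estrogen-repressed genes 12 were higher and 1 lower (12 and 1 adjusted over the list alone). The adjusted p of the set test for these 5 lists was 1.4e-21, 9.4e-16, 4.8e-13, 7.7e-17 and 1.6e-07, and with an estimated correlation the adjusted p was 0.12 for replication, 0.18 for mitosis, 0.11 for repair and 0.028 for each of the other 2.

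Most genes that fulvestrant lowered were among those that estradiol raised. Of 416 genes lower with fulvestrant 390 (93.8%) were higher with estradiol (52.7 expected for independent lists), which is 21.4% of the 1825 genes that estradiol raised. Of 71 genes higher with fulvestrant 60 (84.5%) were lower with estradiol (5.5 expected), and no gene changed in the same direction in both. Across all genes the 2 fold changes had a Pearson r of -0.37 (Spearman rho -0.47) and a covariance of -0.0398. Both comparisons use the 3 vehicle libraries, which alone gave an r of 0.51 (0.48 to 0.54) and a covariance of 0.0229 in 20 simulated sets without any change. The observed covariance differed from that level by -0.0627. Without vehicle replicates 1, 2 and 3 the r was -0.178, -0.206 and -0.183, and among genes with at least 1 CPM in 3 libraries it was -0.622. No simulated sets were run for these fits. With fewer vehicle libraries the error shared by the comparisons is larger, which raises r without any change in the effects.

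Of the 1825 genes that estradiol raised 1785 (97.8%) were lower when fulvestrant was added to it (406.9 expected), and of the 1120 genes it lowered 1095 were higher (210 expected). These comparisons share the estradiol libraries: r was -0.87, against -0.49 (-0.51 to -0.47) in simulated sets, and the covariance was -0.181, against -0.022. The effects of fulvestrant alone and of both compounds, each against vehicle, had an r of 0.77, against 0.5 (0.48 to 0.54) from the shared vehicle libraries, and a covariance of 0.0661, against 0.0227. They had 357 lower genes (15.2 expected) and 30 higher genes (0.4 expected) in common. Groups of 3 cannot be split into independent parts of at least 2 libraries each, so part of the excess over the expected overlap may come from the shared libraries. Where no library was shared, 413 of the 416 genes lower with fulvestrant than with vehicle (99.3%, 92.8 expected) were lower with both compounds than with estradiol, and 68 of the 71 higher genes were higher, with an r of 0.66 across genes.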

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

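The splits of the libraries for fulvestrant against estradiol, the look at which libraries the splits of the interaction set against each other, and the 3 tests of the opposite effects of the compounds were chosen only after the results were seen; the other splits were planned.

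The effect of estradiol differed with and without fulvestrant, by the interaction test, for 1105 genes. Among genes averaging at least 2 CPM the largest differences (log2, the effect with fulvestrant minus that without) were 2.1 for MME, 1.97 for ADAMTS18, 1.8 for SEMA5B, 1.6 for SESN3, 1.45 for TP53INP2 and 1.44 for KCNJ13, and -3.21 for KRT13, -2.8 for H19, -2.76 for GREB1, -2.51 for PDZK1, -2.15 for MSMB and -2.09 for ADORA1. Named in every comparison, PGR had -2.93 and TFF1 -1.52. Of 100 splits of the 12 libraries 3 gave as many genes, the real one included. This share decides nothing, because the other splits hold the treatment effects. The 79 that part the estradiol libraries between the signs of the contrast count the effect of estradiol as spread, and each called 0 genes in edgeR. The 21 that keep these libraries together, the real one included, set them in part against libraries with fulvestrant. The highest count of another split, which also holds treatment effects, was 4068, several times the real count. It and the next (3041) set the estradiol libraries against 5 of the 6 libraries with fulvestrant, where the real split has 3. Being set against 5 does not account for the counts alone, since 2 further splits of that kind called 0 genes in edgeR. For the gene lists 21 of the 100 splits gave as many passing lists as the real 10, with up to 14. These splits too hold the treatment effects, so they do not decide about chance either. The list test with a preset correlation may also be liberal, since 2 of the 10 lists pass with an estimated one.

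The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. Changed genes numbered 2945 for estradiol against vehicle, 487 for fulvestrant against vehicle, 5915 for both compounds against estradiol, 599 for both against vehicle and 5797 for fulvestrant against estradiol, each with 0 as the highest count of another split and therefore 1 split as large, the real one. Both compounds against fulvestrant gave 0 genes in all 10 splits. In the comparisons where replicate numbers pair the libraries, 4 splits part all 3 pairs, and the highest count of the others was again 0. Passing lists numbered 9 for estradiol against vehicle (highest other 10, 6 splits as large), 9 for fulvestrant against vehicle (highest other 8), 9 for both against estradiol (highest other 11, 7 splits), 2 for both against fulvestrant (highest other 9, 7 splits), 8 for both against vehicle (highest other 12, 5 splits) and 9 for fulvestrant against estradiol (highest other 12, 7 splits). The other splits mix the 2 groups in a ratio of 2 to 1, so part of the real difference remains in them. The rest of it counts as spread between replicates, which holds the number of changed genes in those splits down. Their counts of 0 genes therefore decide nothing about chance.

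Of 416 genes lower with fulvestrant alone than with vehicle 390 (93.8%) were raised by estradiol, although none had been added to these cells; they are 21.4% of the 1825 genes raised. Chance values of the shared vehicle libraries would give a correlation of fold changes above 0, and the observed one, -0.37, lay outside the simulated range of 0.48 to 0.54. Slower growth alone is argued against by 18 estrogen-induced genes, outside the replication, mitosis and repair lists, that passed as lower with fulvestrant. This holds only for members whose level does not follow growth, which was not measured, and MYC and MYB are among the 18. Estrogen receptor activity present in vehicle-treated cells, from residual steroid or signalling without ligand, and an effect of fulvestrant itself cannot be told apart here. Of the genes lower with fulvestrant 99.3% were also lower with both compounds than with estradiol, in libraries that share none with the first comparison, which either would give.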

How the results depend on the processing

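Leaving out the 4 libraries of replicate 3 together, and every alternative for fulvestrant against estradiol, were chosen after the data were seen; the other alternatives were planned, and all of them were run. Both compounds against estradiol (5915 genes) and fulvestrant against estradiol (5797) stayed within 1.5 times these counts under every alternative tried, and the slope (-0.024) within its jackknife SE of 0.14, between -0.118 and 0.06. For the same comparisons the replicate block, which models the pairing found there, gave 7385 and 7271 genes. For estradiol against vehicle (2945 genes) the replicate block gave 4821, and single libraries left out gave 1772 to 2810. For fulvestrant against vehicle (487) DESeq2 gave 761, the block 1493, the fit without replicate 3 931 and that of the 6 libraries compared 838, with 178 to 521 without single libraries. For both compounds against vehicle (599) DESeq2 gave 924, the block 1676 and the fit without replicate 3 1481, with 257 to 883 without single libraries. For the interaction (1105) the block gave 2729, with 557 to 1791 without single libraries. Both compounds against fulvestrant gave 0 genes everywhere except 1 with DESeq2. The correlation of the effects of estradiol and fulvestrant (-0.37, jackknife SE 0.2) was -0.622 with at least 1 CPM in 3 libraries, which tests fewer genes, and -0.359 to -0.178 without single libraries. The cause of these changes was not tested beyond the loss or gain of libraries. Libraries were not taken as paired in the 3 comparisons with vehicle, where correlations of the same number (0 to 0.22) were not all above 0.1. A weaker pairing is not excluded there, since each fulvestrant library resembled the vehicle library of its own number most (0.07, 0.16 and 0.12). With the block, interferon-stimulated genes and mitochondrially encoded transcripts also passed camera for estradiol against vehicle (both adjusted p = 0.028). For both compounds against vehicle it added hypoxia and glycolysis (0.042) and mitochondrially encoded transcripts (0.0069). Where numbers did pair libraries (0.21 to 0.37), the block changed the lists between both compounds and fulvestrant (2 to 4). It also ended the BCL2 family call of fulvestrant against estradiol (adjusted p = 0.053) and changed no other call of a named gene or list there. In the interaction, which holds vehicle and the paired groups, the block added the cholesterol synthesis list (adjusted p from 0.074 to 0.033) and the hypoxia and glycolysis list (from 0.086 to 0.033), which had an adjusted p of 0.72 and 0.57 with an estimated correlation.

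With an estimated correlation passing lists went from 9 to 2 for estradiol against vehicle, from 9 to 6 for fulvestrant against vehicle, from 9 to 3 for both compounds against estradiol, from 2 to 0 for both against fulvestrant, from 8 to 2 for both against vehicle, from 10 to 2 for the interaction and from 9 to 3 for fulvestrant against estradiol. Without single libraries the lists numbered 9 to 10 for estradiol against vehicle, 7 to 10 for fulvestrant against vehicle, 8 to 9 for both against estradiol, 1 to 7 for both against fulvestrant, 7 to 10 for both against vehicle, 8 to 12 for the interaction and 9 to 10 for fulvestrant against estradiol. Of 432 reported gene values 88 lost their call without some library and 15 under another alternative; of 5142 pairs of value and alternative 4741 kept their side of the threshold, 398 lost it, 3 gained it (ESR1, fulvestrant against vehicle) and 0 reversed. Among ESR1, PGR, GREB1 and TFF1, depth limits PGR most, with 0 to 9 reads in each fulvestrant-containing library.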

Other observations

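The tests of the position of vehicle cells, of the replicate block in the distribution of p-values, of the libraries of replicate 3 left out together, and of the replication and mitosis lists (the chance tests and that without number 3) were chosen only after the results were seen.

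Vehicle-treated cells lay between the estradiol and the fulvestrant-containing groups for most of the strongly responding genes. Of 878 genes at least 2-fold apart between those groups, 613 were higher and 265 lower with estradiol. On a scale where the fulvestrant-containing groups are 0 and estradiol is 1, the median position of vehicle was 0.42 for the first and 0.32 for the second, with 0.19 and 0.59 as the lowest and highest decile of all. Only 4 genes passed as nearer to fulvestrant and 1 as nearer to estradiol than the midpoint. At an unadjusted p under 0.05 in edgeR there were 142 of the 878, a share above the 0.05 that chance gives if vehicle lay at the midpoint. Genes are not independent, so the number off the midpoint is not settled, and no other tool was run on this test. A uniform intermediate state is therefore neither shown nor excluded gene by gene.

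Between both compounds and fulvestrant alone, fewer genes had a small p-value than chance gives (301 against 720.5). A single estimate of the spread shared by the 4 groups is argued against as the cause, since a fit of only the 6 libraries compared gave 210. Differences between replicate numbers that the fit counts as spread are a candidate explanation: with the replicate number as a block 660 genes had an unadjusted p under 0.05. Without the 4 libraries of replicate 3 the number was 934 and without replicate 3 of both compounds alone 693, against 367 without fulvestrant replicate 3 alone, which points to replicate 3 of both compounds. With the block and in these fits 0 genes passed after adjustment, so this bears on the sensitivity of the comparison more than on its count.

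Replication genes stood lower relative to mitosis genes with fulvestrant than with vehicle. The mean log2 level of the 28 replication genes minus that of the 26 mitosis genes was -0.54 ± 0.06 with vehicle, -0.64 ± 0.07 with estradiol, -0.81 ± 0.1 with fulvestrant and -0.77 ± 0.11 with both compounds (mean ± SD, n = 3 libraries each). The 3 vehicle libraries exceeded the 6 fulvestrant-containing ones by 0.25. Since numbers pair fulvestrant with both compounds, these 6 count as 3 pairs, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give, so that it does not exclude chance (this pair of lists was also chosen after all medians had been seen). The difference was 0.19 without the libraries of number 3 and 0.16 with 18 pairs of members matched on expression, which argues against those libraries or scaling by expression level as the whole cause. Chance and a shift of the cells out of S phase both stay open, and no cell cycle fraction was measured. Vehicle and estradiol differed by 0.1 (exact two-sided permutation p = 0.2).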
